A study of Mus musculus with 6 samples.

How the data were processed

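RNA-seq was done on 6 libraries of mouse embryonic stem cells, 3 wild-type and 3 labelled Q-KO, a name that the labels give to ES cells without any of the G1 cyclins. Per the labels' protocols, the cells were grown with LIF, a MEK inhibitor and a GSK3 inhibitor, total RNA was extracted with Trizol, and Illumina libraries were made. The groups were taken from the genotype labels and the replicate numbers from the sample titles. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. They also do not say that samples with the same number share a culture or a day, so no block was used.

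The authors deposited 1 table of FPKM values, with 1 value per gene symbol and library. Per the submitters' processing notes, CASAVA, bcl2fastq 2.16, STAR 2.5, Cufflinks and the mouse build mm9 were used, named there without role or order. The gene annotation, the strand setting and the read depth are not given in the sources used here. FPKM divides the fragments of a gene by its length and by the library's total, so a few very abundant genes can shift all other values of a library. Gene-level FPKM from Cufflinks is an estimate that can fail at loci with many fragments or close copies, and a listed 0 is then not a measured absence. The table held 24043 gene rows after 1 stray header row inside it was dropped. 27 symbols had been turned into dates, and 2 of these occurred more than once. 4462 genes were listed at 0 in all libraries. 123 microRNA and snoRNA genes were among those tested, and FPKM of such short genes is unreliable. No sample column was left unmapped, and no pair of libraries held identical values.

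Absolute depth is unknown, so no counting interval was computed. Where a gene has few fragments, the ratio of its values in 2 libraries takes a preferred value set by 1 fragment in each. These ratios put the depth relative to wild-type replicate 1 at 1.22 and 1.11 for wild-type replicates 2 and 3, and at 1.1, 1.19 and 1.12 for Q-KO replicates 1, 2 and 3. The method was tested on simulated data.

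Values were analysed as log2(FPKM + 1) for the 11573 genes with a mean of at least 1 FPKM over the 6 libraries. A gene low in 1 group can pass this filter through the other group alone, which favours a change toward that group. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 change is Q-KO minus wild-type on this scale, which understates the change of genes with low values. FPKM values are not counts, so no count test was used. The test was run on simulated libraries over 11434 genes, with the real gene means. Noise was normal and independent for each gene, with the spread that limma estimates by drawing on all genes. For the comparison of wild-type with Q-KO it recovered 3 of 47 genes changed 1.5-fold, 25 of 49 changed 2-fold, 46 of 50 changed 4-fold and 46 of 46 changed 8-fold, and 7 of its 127 calls were false. A missing call of a small change is therefore weak evidence that a gene did not change. In the simulation genes did not vary together and no library was shifted. Its shares of recovered genes and of false calls may therefore not hold for the real libraries.

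The test, the samples, the alternatives, 25 gene lists and the rule for named genes were fixed before the data were examined. The lists cover G1 cyclins, S, G2 and M phase cyclins, CDKs and CDK inhibitors, the RB and E2F family, DNA replication and E2F targets, mitosis, pluripotency, primed epiblast, trophectoderm, primitive endoderm and endoderm, mesoderm, ectoderm and neural genes, the two-cell stage, germline, imprinted genes, p53 targets, the ERK, WNT and LIF-STAT3 responses, glycolysis, cholesterol synthesis, DNA methylation enzymes, fibroblast feeder markers, replication-dependent histones and sex-linked genes. For each list the calls were counted over all genes tested and with adjustment over the list alone. The 22 lists with at least 5 tested members were tested with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists. The text names the 5 G1 cyclins, 11 pluripotency and trophectoderm factors chosen in advance, the 8 largest changes in each direction among calls with separate ranges (without predicted, clone-named, microRNA and snoRNA genes), up to 4 called members per list with the largest change, and the most abundant tested member of each list without a call. Any other gene was named after its values were seen. Genes with close copies are called uncertain.

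Alternatives fixed in advance were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, no intensity trend, a robust fit, the replicate number as a block, leaving out each library, and a minimum of a 2-fold change. Added after the data were seen were a term for libraries with Y-linked transcripts, the removal of the 2 genes listed at 0 in 1 group and above 10 FPKM in the other, the removal of chromosomes 8, 11, X and Y, the removal of wild-type replicate 3 together with Q-KO replicate 1, and the removal of trends with gene length or GC content. With the term for Y-linked transcripts, the group difference rests on the Q-KO libraries against wild-type replicate 3 alone, and that lone library is assumed to vary like the others. The reference at hand was of build GRCm38 and not mm9, so no coordinates are given. RefSeq and GENCODE M21 served only for the chromosome and order of genes (99.5% of tested genes had a chromosome) and for transcript length and GC content (95.3% of tested genes). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the other steps.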

Results

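Transcript levels were measured by RNA-seq in mouse embryonic stem (ES) cells of 2 genotypes. ES cells are pluripotent cells derived from the early embryo, and these were grown with leukaemia inhibitory factor (LIF), the MEK inhibitor PD184352 and the GSK3 inhibitor CHIR99021. The wild-type group and the group labelled Q-KO, whose genotype label says that the cells have no G1 cyclin, held 3 libraries each. The comparison asks how the transcriptome of the libraries labelled Q-KO differs from that of the wild-type libraries. The values were FPKM per gene symbol. Their sum per library ranged from 525134 to 641715, and between 11032 and 11591 genes had at least 1 FPKM in a library. The number of fragments behind these values was not given in the sources used here. The low values put the relative depth of the other libraries at 1.1 to 1.22 times that of wild-type replicate 1. Across genes, Pearson's r of log2(FPKM + 1) was 0.942 to 0.973 within the wild-type group, 0.964 to 0.979 within the Q-KO group and 0.924 to 0.955 between groups. Wild-type replicate 2 was closer to each Q-KO library (r of 0.951, 0.951 and 0.949) than to wild-type replicate 3 (0.942). Wild-type replicate 3 stood apart from the other wild-type libraries. Wild-type replicate 3 had Y-linked transcripts, as did the 3 Q-KO libraries, whereas wild-type replicates 1 and 2 were listed at 0 for all 5 Y-linked genes examined.

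Of the 5 G1 cyclins, Ccnd3, Ccnd1 and Ccne2 fell in the libraries labelled Q-KO, and Ccne1 did not. Ccnd3 was at 85.6 ± 48.2 FPKM in wild-type and 10.8 ± 2.45 FPKM in Q-KO libraries (mean ± SD, n = 3 per group, as for all means below), and fell by 2.76 on the log2 scale (SE 0.35, limma adjusted p = 0.0101). Ccnd1 went from 30.1 ± 9.80 to 8.89 ± 1.04 FPKM and fell by 1.61 (SE 0.23, limma adjusted p = 0.0124). Ccne2 went from 6.83 ± 0.97 to 2.98 ± 0.15 FPKM and fell by 0.97 (SE 0.16, limma adjusted p = 0.0182). Ccne1 was higher in each Q-KO library (65.3, 73.5 and 87.3 FPKM) than in any wild-type library (55.9, 53.9 and 37.5 FPKM), with a log2 change of 0.62 (SE 0.19) that did not pass the threshold (limma adjusted p = 0.113). Ccnd2 was below the filter, at 0.179 ± 0.124 FPKM in wild-type and 0.398 ± 0.133 FPKM in Q-KO libraries. A gene-level FPKM covers all exons of a gene, so reads from exons outside a deleted part remain in it, and these values alone do not show which alleles were deleted. Because Ccne1 ran against the genotype label, every direction below is that of the libraries labelled Q-KO. Without Q-KO replicate 2 or Q-KO replicate 3, 0 of the 3 calls passed (adjusted p 0.0782 to 0.112 and 0.051 to 0.0665), without wild-type replicate 1 only Ccnd3 did (adjusted p = 0.0126), and without Q-KO replicate 1 Ccne2 was lost (adjusted p = 0.0634). In a model with a term for Y-linked transcripts, which was chosen after the data were seen and compares the Q-KO libraries with wild-type replicate 3 alone, Ccne1 rose by 0.98 (adjusted p = 0.0292) and the call of Ccne2 was lost (adjusted p = 0.0534).

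**Figure D1:**
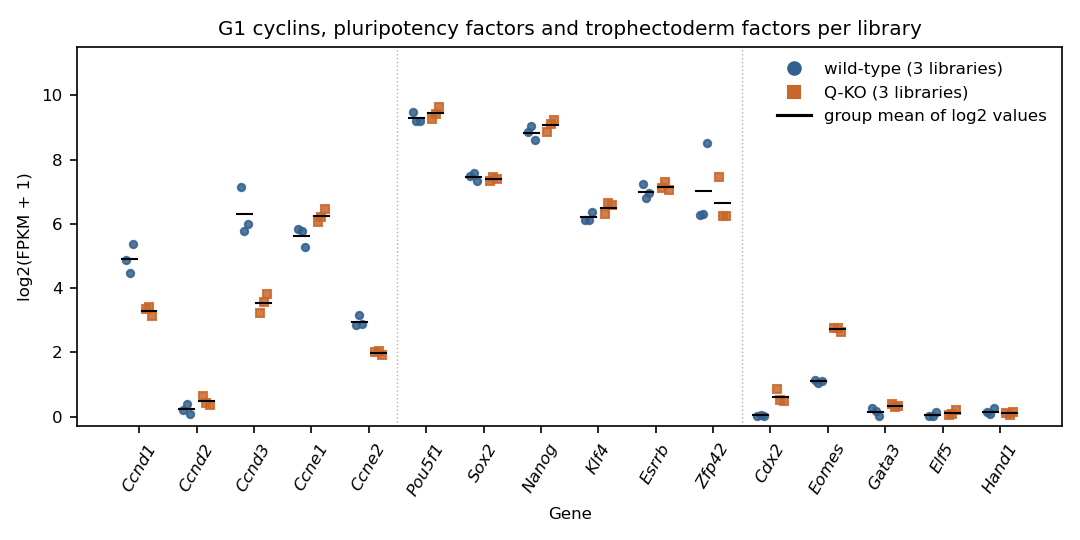
Levels of the 5 G1 cyclins, 6 pluripotency factors and 5 trophectoderm factors in each library, as log2(FPKM + 1) on the vertical axis. Circles are the 3 wild-type libraries, squares the 3 Q-KO libraries and bars the group means of the log2 values. Ccnd1, Ccnd3 and Ccne2 were lower and Eomes was higher in every Q-KO library, while both groups overlap for Pou5f1, Sox2 and Nanog.

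Of the 11573 genes tested, 470 (4.1%) differed between the groups. Of these, 352 were higher and 118 lower in the Q-KO libraries, so that 74.9% of the calls were rises. The unadjusted p was under 0.05 for 2493 genes. The ranges of the groups did not overlap for 3201 genes (27.7%), where chance gives 10%. The largest rises with separate ranges included Stra8, a gene required for entry into meiosis, which went from 13.7 ± 20.02 to 162 ± 51.7 FPKM (log2 change 4.44, SE 0.88, adjusted p = 0.0343). Its wild-type spread came from wild-type replicate 2, at 36.9 FPKM against 2.67 and 1.70. Rhox13, an X-linked homeobox gene, went from 0.857 ± 0.328 to 23.2 ± 3.91 FPKM (log2 change 3.71, SE 0.20, adjusted p = 3.53e-04). Gsto1, a glutathione S-transferase, went from 36.4 ± 18.7 to 323 ± 19.07 FPKM (log2 change 3.27). The other large rises were those of Mid1 (3.71), which encodes a microtubule-associated ubiquitin ligase, the aldo-keto reductase gene Akr1cl (3.71), Igfbp7 (3.28) and the citrate transporter gene Slc13a5 (3.05). Eef1a1, a translation elongation factor that every cell uses, was listed at 0 in the 3 wild-type libraries and at 5333, 5550 and 5903 FPKM in the Q-KO libraries, and no fold change is given for it. The largest falls were those of the oocyte homeobox gene Obox6 (-3.17), Ccnd3 and Bst2, which encodes the antiviral membrane protein tetherin. Bst2 went from 81.4 ± 7.48 to 13.8 ± 5.67 FPKM (log2 change -2.55, SE 0.27, adjusted p = 0.00474). Vax2os (-1.81), Ndrg2 (-1.67), the carbonyl reductase gene Cbr3 (-1.65), the POU factor gene Pou2f3 (-1.65) and the caldesmon gene Cald1 (-1.63) followed. Values of Rhox13, Akr1cl, Obox6 and Eef1a1 are uncertain because these genes have close copies, and that of Vax2os because strand-specific counting was not stated. Without Q-KO replicate 2 the calls of Stra8, Mid1, Gsto1 and all of these falls but Bst2 were lost (adjusted p 0.0595 to 0.171), and without Q-KO replicate 3 those of the same 3 rises and of Obox6, Ccnd3, Cbr3, Pou2f3 and Cald1. Without wild-type replicate 1 those of Stra8, Obox6, Vax2os and Pou2f3 were lost, without Q-KO replicate 1 those of Stra8 and Obox6, and without wild-type replicate 2 that of Obox6. The count of genes past the threshold was 94 without wild-type replicate 1, 187 without Q-KO replicate 1, 28 without Q-KO replicate 2, 85 without Q-KO replicate 3, and 894 with the term for Y-linked transcripts. The count of falls alone was 78 without wild-type replicate 2. Of the 49 named genes past the threshold, 8 stayed past it in all 6 leave-one-out fits: Akr1cl, Asz1, Bst2, Eomes, Igfbp7, Rhox13, Slc13a5 and Eef1a1, whose call rests on values listed at 0, which can stand for a failed estimate. With all 6 libraries kept, 12 of the 49 calls were lost with no filter on low values (Stra8, Obox6, Pou2f3, Cdkn1b, E2f8, Rbl1, Tbx3, Rhox9, Nefm, Meg3, Rian and Gnas), 8 with the replicate number as a block (Ccnb1, Rbl1, Tbx3, Tfap2c, Rian, Fgl1, Hk1 and Mmp2), 12 with the term for Y-linked transcripts (Ccne2, Ccnb1, Cdkn1b, E2f8, Rbl1, Cenpf, Mki67, Tbx3, Rhox9, Gnas, Hk1 and Mmp2), and 5 after a GC trend was removed (Tbx3, Nefm, Rian, Gnas and Mmp2). A fit with no intensity trend lost 4 (Ccnb1, Rbl1, Gnas and Hk1) and a robust fit 3 (Stra8, Obox6 and Rhox9). A pseudocount of 0.1 (Fgl1 and Hk1), quantile normalization or median-of-ratios scaling (Gnas and Fgl1 in each) and a mean of at least 5 FPKM (Rbl1 and Hk1 among the genes still tested) lost 2 each, and removal of a length trend 1 (Meg3). The share of rises depended on the scaling, at 54.0% after quantile normalization, 51.5% after a trend with gene length was removed and 56.4% after a trend with GC content was removed.

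Genes of mitosis were lower in the Q-KO libraries. Of 22 tested members of the list, 21 had a log2 change below 0 and 8 fell over all genes tested, while 17 fell when adjusted over the list alone. The median log2 change of the list was -0.65. The cell cycle genes with the largest falls in this list were Cenpf, a kinetochore protein (-1.20), Hmmr, a spindle protein (-1.14), the proliferation antigen gene Mki67 (-1.04) and the DNA topoisomerase gene Top2a (-1.01). Top2a went from 211 ± 18.0 to 104 ± 6.46 FPKM (SE 0.13, adjusted p = 0.0101), and Mki67 from 21.4 ± 1.2 to 10.03 ± 2.14 FPKM (SE 0.17, adjusted p = 0.0173). The list passed the camera set test with a preset correlation of 0.01 (adjusted p = 1.95e-16). It did not pass with the correlation estimated from these libraries (adjusted p = 0.392). Of the 4 named genes, 0 passed without Q-KO replicate 2 (adjusted p 0.0668 to 0.121), and only Hmmr and Top2a passed without Q-KO replicate 3, without wild-type replicate 1 or with the term for Y-linked transcripts. The model with that term rests on wild-type replicate 3, in which genes of chromosomes 8 and 11 were higher. Hmmr and Top2a, unlike Cenpf and Mki67, were among the genes removed with chromosomes 8, 11, X and Y. Their falls in that model may therefore hold part of this excess.

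Genes of DNA replication went in both directions. None of the 30 tested members of the list of DNA replication and E2F targets passed limma's test, over all genes or adjusted over the list alone (7 had an unadjusted p under 0.05, 3 higher and 4 lower), and the median log2 change was -0.04 (camera adjusted p = 0.275). The members furthest from 0, named after their values were seen, were Rpa2 (0.61, adjusted p = 0.11) and Mcm10 (-0.59, adjusted p = 0.051), both with separate ranges. Pcna, the DNA polymerase clamp, was at 412 ± 47.2 FPKM in wild-type and 384 ± 30.2 FPKM in Q-KO libraries (adjusted p = 0.745). Among the S, G2 and M phase cyclins, 1 of 4 tested members fell over all genes and 3 when adjusted over the list alone. The member that fell over all genes was Ccnb1, cyclin B1, which went from 186 ± 5.76 to 125 ± 5.02 FPKM (log2 change -0.57, SE 0.12, adjusted p = 0.037). Among CDKs and CDK inhibitors, 1 of 11 tested members fell, in both counts. This was Cdkn1b, the inhibitor p27, which went from 20.4 ± 2.10 to 11 ± 1.85 FPKM (log2 change -0.84, SE 0.16, adjusted p = 0.0323). In the RB and E2F family, 2 of 13 tested members fell, in both counts. E2f8, a repressor of the E2F family, changed by -1.18 (adjusted p = 0.0488), and Rbl1, which encodes the pocket protein p107, by -0.68 (adjusted p = 0.049). Neither of these lists passed camera (adjusted p = 0.923 for CDKs and CDK inhibitors and 0.268 for the RB and E2F family). In both lists the median was above 0 (0.09 and 0.08) although camera's direction was down, and the mean was 0.06 and -0.12. The calls of Ccnb1 and Rbl1 were lost in each of the 6 leave-one-out fits (highest adjusted p 0.193 and 0.229, without Q-KO replicate 2). Those of Cdkn1b and E2f8 held only without wild-type replicate 3.

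**Figure D2:**
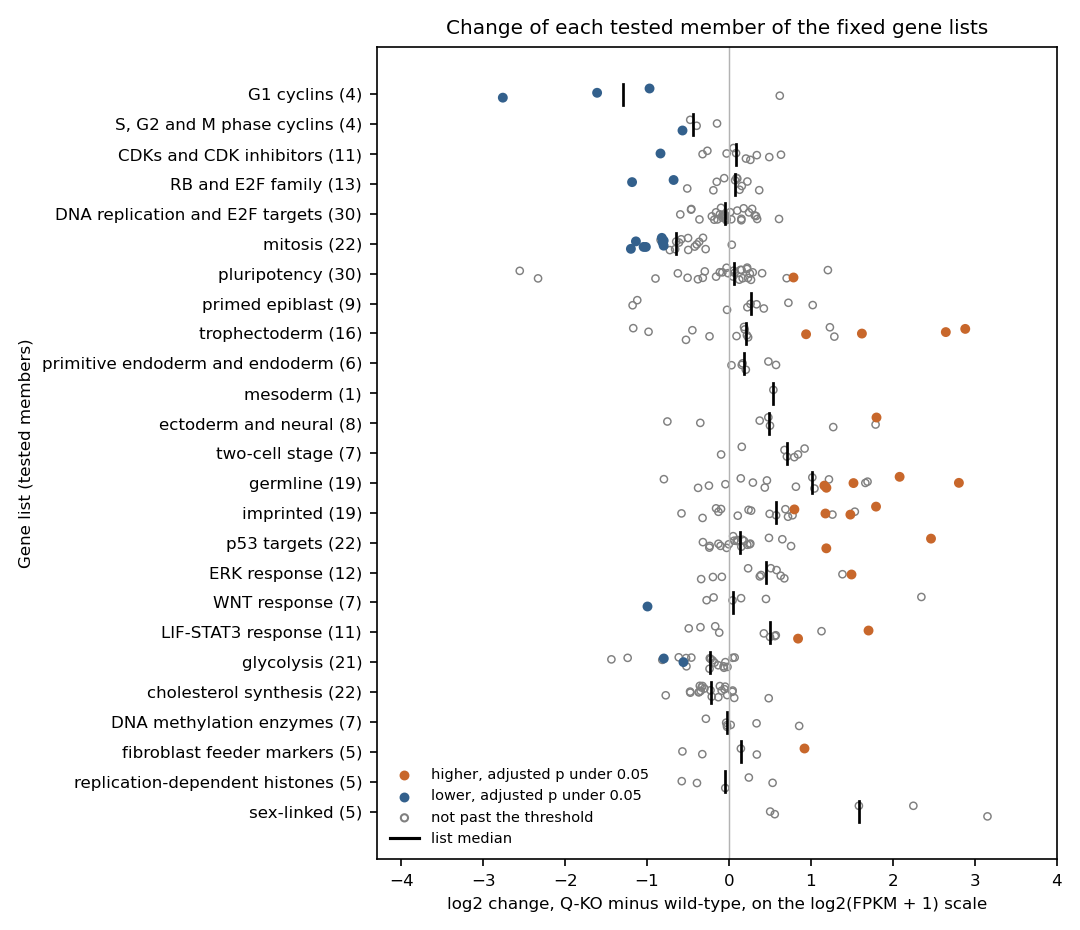
Log2 change (Q-KO minus wild-type, log2(FPKM + 1) scale, horizontal axis) of each tested member of the 25 fixed gene lists, with the number of tested members in brackets. Filled points passed limma's test (orange higher, blue lower in Q-KO libraries), open points did not, and bars are list medians. Of the 22 mitosis genes 21 lie below 0, with 8 past the threshold, and 5 of 19 germline genes passed as higher.

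None of the 6 pluripotency factors chosen in advance passed the test. Pou5f1, the gene of Oct4, was at 632 ± 74.1 FPKM in wild-type and 698 ± 92.1 FPKM in Q-KO libraries (log2 change 0.14, SE 0.16, adjusted p = 0.664). Sox2 was at 176 ± 14.4 and 167 ± 7.51 FPKM (-0.08, SE 0.13, adjusted p = 0.753), and Nanog at 461 ± 65.8 and 536 ± 66.2 FPKM (0.22, SE 0.17, adjusted p = 0.486). Klf4 (0.29, SE 0.15) and Esrrb (0.15, SE 0.15) did not pass either. The naive-state marker Zfp42 was at 173 ± 165 and 109 ± 58.6 FPKM, and its wild-type spread came from wild-type replicate 3, at 363 FPKM against 76.6 and 78.9. Without that library its log2 change was 0.36 in place of -0.38, and neither passed. Of the 30 tested members of the pluripotency list, 1 rose and 0 fell, while 1 rose and 3 fell when adjusted over the list alone. The 3 that fell there, named after their values were seen, were Lefty2 (-2.55), Lefty1 (-2.33) and Tcl1 (-0.897), each with separate ranges. Over all genes these 3 did not pass (adjusted p = 0.0834, 0.064 and 0.0596). Values of Lefty1 and Lefty2 are uncertain because these genes are close copies of each other. The member that rose was the T-box factor gene Tbx3, from 28.4 ± 4.77 to 49.3 ± 3.6 FPKM (log2 change 0.79, SE 0.16, adjusted p = 0.0346). The list did not pass camera (adjusted p = 0.716). Its median (0.06) was above 0, while its mean (-0.10) and camera's direction were below. The call of Tbx3 held in 1 of the 6 leave-one-out fits, that without wild-type replicate 3, and was lost with the term for Y-linked transcripts (adjusted p = 0.11).

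Trophectoderm genes rose in part. Of the 28 members of the list 16 were tested, of which 4 rose and 0 fell over all genes and 6 rose when adjusted over the list alone. Eomes, a T-box factor of trophoblast stem cells, went from 1.16 ± 0.08 to 5.64 ± 0.34 FPKM (log2 change 1.62, SE 0.15, adjusted p = 0.00398). Tfap2c, an AP-2 factor, went from 17.2 ± 1.67 to 34.2 ± 5.23 FPKM (0.94, SE 0.16, adjusted p = 0.0195). Rhox6 (2.88) and Rhox9 (2.65) belong to a homeobox cluster on the X chromosome that is expressed in placenta and germ cells, and their values are uncertain because these genes have close copies. Cdx2 (0.031 ± 0.016 and 0.547 ± 0.225 FPKM), Gata3 (0.113 ± 0.099 and 0.275 ± 0.041 FPKM), Elf5 (0.050 ± 0.045 and 0.088 ± 0.062 FPKM) and Hand1 (0.122 ± 0.074 and 0.078 ± 0.030 FPKM) were below the filter and were not tested. The list did not pass camera (adjusted p = 0.222). Eomes stayed past the threshold in all 6 leave-one-out fits (highest adjusted p = 0.0441, without Q-KO replicate 2). Of the other 3 calls, 0 passed without Q-KO replicate 2 or without wild-type replicate 1, only Rhox6 passed without Q-KO replicate 3, and Rhox9 was also lost without Q-KO replicate 1, without wild-type replicate 2 and with the term for Y-linked transcripts (adjusted p 0.0519, 0.0753 and 0.104).

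Other lineage lists held few calls. Among ectoderm and neural genes, 1 of 8 tested members rose, and 2 rose and 1 fell when adjusted over the list alone. The neurofilament gene Nefm went from 1.46 ± 1.1 to 7.39 ± 2.91 FPKM (log2 change 1.80, SE 0.35, adjusted p = 0.0338), a call that held only without wild-type replicate 1 or wild-type replicate 3 among the 6 leave-one-out fits (highest adjusted p = 0.165, without Q-KO replicate 2). None of 9 tested genes of the primed epiblast passed limma's test over all genes (3 had an unadjusted p under 0.05), and 2 rose when adjusted over the list alone. Nodal was at 31.5 ± 7.96 FPKM in wild-type and 41.9 ± 3.62 FPKM in Q-KO libraries (adjusted p = 0.227). In either count, 0 of 6 tested genes of primitive endoderm and endoderm, 0 of 1 of mesoderm, 0 of 7 of the two-cell stage and 0 of 7 DNA methylation enzymes passed limma's test, and the unadjusted p was under 0.05 for 1, 0, 0 and 1 of them. Their most abundant members were Sparc (132 ± 45.1 and 148 ± 23.7 FPKM), Gsc (3.85 ± 0.81 and 6.49 ± 3.44 FPKM), Eif1a (101 ± 10.1 and 94.1 ± 6.2 FPKM, uncertain because it has close copies) and Uhrf1 (189 ± 20.8 and 185 ± 9.48 FPKM). Camera gave adjusted p of 0.379 for ectoderm and neural, 0.56 for primed epiblast, 0.56 for primitive endoderm and endoderm, 0.375 for two-cell stage and 0.877 for DNA methylation enzymes. The last list had a median of -0.02 and a mean of 0.12.

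Part of the germline list was higher in the Q-KO libraries. Of 19 tested members, 15 had a log2 change above 0 and 4 below 0, 5 rose and 0 fell over all genes, and 11 rose when adjusted over the list alone, with a median log2 change of 1.02. The wild-type libraries differed among themselves, as wild-type replicate 2 was the highest of the 3 for 15 of the 19. Dazl, a germ cell RNA-binding protein named after its values were seen, was at 19.5, 129 and 17.6 FPKM in wild-type replicates 1, 2 and 3 and at 90.6, 126 and 143 FPKM in the Q-KO libraries (adjusted p = 0.193). Hormad1, also named after its values were seen, was lower in each Q-KO library than in any wild-type library (log2 change -0.79, adjusted p = 0.195). Sycp3, Ddx4 and Piwil2, named in the same way, were at least 2-fold higher in wild-type replicate 2 than in the other wild-type libraries. Asz1, a germ cell gene of the piRNA pathway, went from 0.595 ± 0.549 to 9.78 ± 0.72 FPKM (log2 change 2.81, SE 0.24, adjusted p = 0.00267). Rhox2a changed by 2.08, and is uncertain because of its close copies. Taf7l, a germ cell paralogue of a general transcription factor subunit, changed by 1.52, and the testis ADP/ATP carrier gene Slc25a31 by 1.19. The list passed camera (adjusted p = 1.9e-04) but not with an estimated correlation (adjusted p = 0.686). Asz1 stayed past the threshold in all 6 leave-one-out fits. Rhox2a, Taf7l and Slc25a31 were lost without Q-KO replicate 2, Q-KO replicate 3 or wild-type replicate 1 (adjusted p up to 0.128), and Slc25a31 also without Q-KO replicate 1 (adjusted p = 0.0634).

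Part of the imprinted list was higher as well. Of 19 tested members, 14 had a log2 change above 0 and 5 below 0, 4 rose and 0 fell over all genes, and 6 rose when adjusted over the list alone, with a median log2 change of 0.57. The non-coding RNA gene Meg3 went from 37.3 ± 4.77 to 110 ± 37.3 FPKM (log2 change 1.48, SE 0.25, adjusted p = 0.0219), and Rian, a non-coding RNA gene of the same maternally expressed cluster, from 53.6 ± 11.2 to 123 ± 24.6 FPKM (1.18, SE 0.20, adjusted p = 0.022). Nnat, which encodes neuronatin, changed by 1.80 (adjusted p = 0.0155). Gnas, the gene of a G protein alpha subunit, changed by 0.80 (adjusted p = 0.0396), with overlapping transcripts at its locus that a gene-level value does not separate. The list passed camera (adjusted p = 0.0152) but not with an estimated correlation (adjusted p = 0.392), and not without the filter on low values (median 0.29, adjusted p = 0.119). All 4 calls were lost without Q-KO replicate 2 (adjusted p 0.108 to 0.2) or Q-KO replicate 3 (0.0624 to 0.111). Those of Nnat and Gnas were lost without Q-KO replicate 1 (0.0572 and 0.0949), those of Meg3 and Gnas without wild-type replicate 1 (0.0691 and 0.101), and those of Meg3 and Rian without wild-type replicate 2 (0.0535 and 0.0533). With all 6 libraries kept, Gnas was lost under 6 alternatives (adjusted p 0.0501 to 0.111), Rian with no filter, with the replicate block and after a GC trend was removed (0.0555, 0.0555 and 0.0502), and Meg3 with no filter and after a length trend was removed (0.0614 and 0.0562).

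Single members of the signalling and stress lists rose or fell, and none of these lists passed camera. Among p53 targets, 2 of 22 tested members rose (3 when adjusted over the list alone). The proapoptotic gene Pmaip1 went from 5.05 ± 2.157 to 31.5 ± 8.34 FPKM (log2 change 2.47, SE 0.30, adjusted p = 0.0095), and the antiproliferative gene Btg2 from 17.1 ± 2.26 to 40.3 ± 4.78 FPKM (1.19, SE 0.15, adjusted p = 0.0102). Among genes of the ERK response, 1 of 12 tested members rose, in both counts. This was the ETS factor gene Etv4, from 4.5 ± 0.69 to 14.3 ± 1.14 FPKM (1.48, SE 0.15, adjusted p = 0.00464). Of 7 tested genes of the WNT response, 1 fell over all genes, and 1 rose and 1 fell when adjusted over the list alone. The WNT feedback inhibitor Notum went from 28.7 ± 2.39 to 13.9 ± 1.1 FPKM (-0.99, SE 0.13, adjusted p = 0.0108). In the LIF-STAT3 response, 2 of 11 tested members rose over all genes, and 6 rose and 1 fell when adjusted over the list alone. Junb, a subunit of AP-1, changed by 1.70 (adjusted p = 0.0141) and Fgl1 by 0.84 (adjusted p = 0.0436). Camera's adjusted p was 0.297 for p53 targets, 0.222 for the ERK response, 0.691 for the WNT response (median 0.04 and mean 0.22 with camera's direction down) and 0.222 for the LIF-STAT3 response. Without genes of chromosomes 8, 11, X and Y the median of the LIF-STAT3 list was -0.12 in place of 0.50. Without Q-KO replicate 2 none of these 6 calls passed limma's test (adjusted p 0.0564 to 0.176). Those of Junb and Fgl1 were also lost without Q-KO replicate 1, Q-KO replicate 3 or wild-type replicate 1, that of Fgl1 without wild-type replicate 2 (0.0542), that of Notum without Q-KO replicate 3 or wild-type replicate 1 (0.051 and 0.0506), and that of Pmaip1 without Q-KO replicate 3 (0.0535).

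Genes of glycolysis and of cholesterol synthesis were lower as lists. In glycolysis, 19 of 21 tested members had a log2 change below 0 and 2 fell, in both counts, with a list median of -0.23. Pfkm, a subunit of phosphofructokinase, went from 20.04 ± 1.52 to 11.1 ± 1.09 FPKM (log2 change -0.80, SE 0.14, adjusted p = 0.0219), and the hexokinase gene Hk1 from 34.3 ± 2.93 to 22.9 ± 0.68 FPKM (-0.56, SE 0.12, adjusted p = 0.0492). In cholesterol synthesis, 18 of 22 tested members were below 0 and none passed limma's test in either count (5 had an unadjusted p under 0.05), with a median of -0.22. Its most abundant member Fdps was at 170 ± 16.7 FPKM in wild-type and 170 ± 44.3 FPKM in Q-KO libraries. Both lists passed camera (adjusted p = 1.9e-04 and 0.00142), and neither did with an estimated correlation (adjusted p = 0.686 for each). Against wild-type replicate 3 alone, in the model with the term for Y-linked transcripts, their medians were 0.04 (adjusted p = 0.673) and -0.13 (adjusted p = 0.324). The call of Hk1 was lost in each of the 6 leave-one-out fits, and that of Pfkm held only without wild-type replicate 2 or wild-type replicate 3 (highest adjusted p 0.206 and 0.146, without Q-KO replicate 2).

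Markers of other cells and of library make-up were measured in the same way. Of 5 tested markers of fibroblast feeder cells, 1 rose, in both counts. Mmp2, a matrix metalloproteinase, went from 1.21 ± 0.19 to 3.19 ± 0.45 FPKM (log2 change 0.92, SE 0.17, adjusted p = 0.0306), a call that held only without wild-type replicate 2 or wild-type replicate 3 (highest adjusted p = 0.152, without Q-KO replicate 2). The fibroblast collagen gene Col1a1, named after its values were seen, was at 1.86 FPKM in Q-KO replicate 1 and at 0.168 FPKM or less in the other 5 libraries. The feeder list did not pass camera (adjusted p = 0.96), with a median of 0.14 and camera's direction down. With no filter on low values it passed, with direction up (median 0.19, adjusted p = 0.0471). None of 5 tested replication-dependent histone genes passed limma's test in either count (1 had an unadjusted p under 0.05, camera adjusted p = 0.716), and the most abundant, Hist1h2bc, was at 3.09 ± 1.27 and 3.75 ± 1.09 FPKM, uncertain because it has close copies.

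The sex-linked list separated the wild-type libraries from each other. Eif2s3y was listed at 0 in wild-type replicates 1 and 2, at 74.2 FPKM in wild-type replicate 3, and at 47.1, 34.4 and 30.3 FPKM in the Q-KO libraries. Ddx3y, named after its values were seen, was at 0, 0 and 17.8 FPKM in the wild-type libraries and at 17.2, 10.1 and 9.05 FPKM in the Q-KO libraries. Xist was at 0.07 FPKM or less in all 6. None of the 5 tested members passed limma's test in either count (1 had an unadjusted p under 0.05), and the list did not pass camera (adjusted p = 0.167). Wild-type replicate 3 also had higher levels of genes on chromosomes 8 and 11. Each gene was set against its mean over all 6 libraries, so an excess in a single library is understated and lowers the values of the other 5. Over genes with a mean of at least 5 FPKM, the chromosome medians of wild-type replicate 3 relative to all autosomes were 0.24 and 0.23 log2 units. Those of its other 17 autosomes lay between -0.07 and 0.02. The autosomes of the other 5 libraries lay between -0.12 and 0.10. Chromosome 8 was at 0.067 in Q-KO replicate 1, against -0.118 and -0.108 in Q-KO replicates 2 and 3 and -0.053 and -0.036 in wild-type replicates 1 and 2. The count of genes past the threshold was 566 without wild-type replicate 3, 352 without genes of chromosomes 8, 11, X and Y, and 466 without both wild-type replicate 3 and Q-KO replicate 1.

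**Figure D3:**
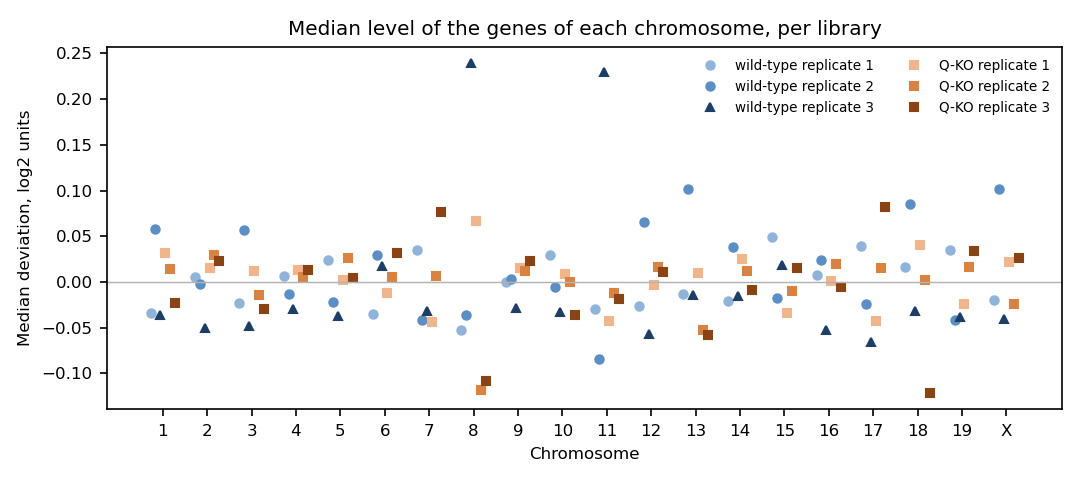
Median deviation in log2 units of the genes of each chromosome in each library, over genes with a mean of at least 5 FPKM, by chromosome on the horizontal axis. Deviations are from the mean of each gene over all libraries, relative to all autosomes. Blue points are the wild-type libraries (triangles, wild-type replicate 3) and orange squares the Q-KO libraries. Wild-type replicate 3 lies at 0.24 on chromosome 8 and 0.23 on chromosome 11, above the autosomes of the other 5 libraries.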

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

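The alternatives named with Y-linked transcripts, chromosomes, gene length, GC content and the joint removal of 2 libraries were chosen after the data were seen, and the others were planned. No called named gene changed direction under any alternative run, but many calls were lost, with fewer samples and with all of them. Of 49 named calls, 31 passed without Q-KO replicate 1, 8 without Q-KO replicate 2, 15 without Q-KO replicate 3, and 22, 37 and 46 without wild-type replicates 1, 2 and 3. With all 6 libraries, 20 of the 49 were lost under at least 1 alternative, among them 12 with no filter on low values, 12 with the term for Y-linked transcripts, 8 with the replicate block, 5 after the GC trend was removed and 4 with no intensity trend. Over all named genes and alternatives, 1049 results kept direction and side of the threshold, 199 were weaker, 4 stronger and 18 reversed. For the gene lists these numbers were 414, 8, 4 and 23. The number of genes past the threshold (470, with 352 higher and 118 lower) ranged from 28 to 566 over the fits with a library left out (higher 25 to 412, lower 3 to 154). It was 280 (225 and 55) with a minimum 2-fold change and 266 (188 and 78) with a mean of at least 5 FPKM, where fewer genes can pass. It was 894 (663 and 231) with the term for Y-linked transcripts. The lower genes numbered 210 after quantile normalization, 298 after the length trend was removed and 199 after the GC trend was removed. These 3 settings also moved the median change of all tested genes from 0.072 to -0.028, -0.022 and -0.027. With the replicate number as a block (replicate block), 333 genes passed (245 higher, 88 lower), of which 287 were among the 470. The deviations of same-numbered samples correlated at -0.028, 0.012 and 0.022, and no sample correlated best with its own number. These values give no sign that the numbers pair the samples, but so few samples per group cannot exclude a shared culture or day.

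Of the G1 cyclins, Ccnd1 ranged from -1.831 to -1.376, Ccnd3 from -3.028 to -2.336 and Ccne2 from -1.028 to -0.87. These ranges cover the fits with 1 library left out and the fit without both wild-type replicate 3 and Q-KO replicate 1. With the term for Y-linked transcripts Ccne2 was at -0.887 (not past the threshold) and Ccne1 at 0.977 (past it). With an estimated correlation 5 lists no longer passed, at unchanged medians: mitosis (-0.651), germline (1.017), imprinted (0.575), glycolysis (-0.234) and cholesterol synthesis (-0.218). Those of mitosis and germline passed under every other alternative. The imprinted median was 0.29 and not past without a filter, where more low genes enter, and with the term for Y-linked transcripts the glycolysis and cholesterol medians were 0.038 and -0.131 and not past.

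Results that reversed were not past the threshold as designed, and 1 of them, the feeder list with no filter, was past it after it reversed. With the term for Y-linked transcripts these were Sox2 (0.049), Pcna (0.099), Eif1a (0.063), Fdps (0.144), Uhrf1 (0.128), Eif2s3y (-1), the sex-linked list (-0.57) and the DNA methylation list (0.128). Pou5f1 was at -0.03 after length and -0.018 after GC trend removal. For lists, the direction is that of camera and the value the median: DNA methylation at -0.009 (length trend) and -0.062 (quantile), pluripotency at 0.016 (quantile), ectoderm at 0.017 (no filter), CDKs at 0.234 (mean of at least 5 FPKM), LIF-STAT3 at -0.119 (without chromosomes 8, 11, X and Y), and feeder markers at 0.19 (no filter, adjusted p = 0.0471), 0.101 (median-of-ratios), 0.145 (replicate block) and 0.142 (length trend). The next ranges cover the fits with 1 library left out and the fit without both wild-type replicate 3 and Q-KO replicate 1. They were -0.216 to 0.149 for Fdps, -0.157 to 0.45 for Hist1h2bc, -0.101 to 0.057 for Uhrf1 and -0.786 to 0.358 for Zfp42. For lists they were 0.036 to 0.193 for CDKs, -0.09 to 0.165 for DNA methylation, -0.218 to 0.23 for WNT and -0.125 to 0.289 for feeder markers. Those of primed epiblast and two-cell genes were 0.06 to 0.552 and 0.093 to 1.162. The lowest values for Hist1h2bc, primed epiblast and two-cell genes came from the joint removal, and the two-cell list reversed only there. Where no reason is given, the cause was not tested. Absolute depth is unknown, which leaves the error of low values open.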

Other observations

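The 4 added gene lists (Rhox, lysosome, MHC class I, and serine, glycine and proline synthesis), the named genes and the tests of explanations in this part were chosen only after the results were seen. The Rhox homeobox genes, an X-linked cluster expressed in reproductive tissues, were higher in the Q-KO libraries. Of 30 members 20 were tested and all 20 rose, with a median log2 change of 1.77. Most of these 20 had a wild-type mean under 1 FPKM and passed the filter only through their Q-KO values, which favours a rise. The number past the threshold was 3 without Q-KO replicate 2, 5 without wild-type replicate 1, 6 without Q-KO replicate 3, 16 without Q-KO replicate 1, 18 without wild-type replicate 2 and 20 without wild-type replicate 3, and in each of these fits all 20 had a change above 0. With all 6 libraries and the same 20 genes tested, 18 to 20 passed under the alternatives run, with 18 under quantile normalization and with the term for Y-linked transcripts. With no filter on low values 18 of 29 passed and all 29 had a change above 0. With a mean of at least 5 FPKM 5 of 5 passed, and these reached that mean only through their Q-KO values. Rhox1 went from 4.34 ± 1.53 to 22.2 ± 2.78 FPKM (mean ± SD, n = 3 per group) and Rhox13 from 0.857 ± 0.328 to 23.2 ± 3.91 FPKM. Rhox6, Rhox9 and Rhox2a are also in the fixed lists. Values of single Rhox2 and Rhox4 copies and of Rhox6, Rhox9 and Rhox13 are uncertain, since their reads can be split between copies. The family passed camera with a preset correlation (adjusted p = 8.37e-22 over the 4 added lists), but not with an estimated correlation (adjusted p = 0.174).

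Lysosomal genes were higher, with 6 of 42 tested members past the threshold, 10 when adjusted over the list alone, and a median log2 change of 0.38. Psap, which encodes the precursor of the saposins, went from 104 ± 7.18 to 199 ± 26.9 FPKM, and the progranulin gene Grn from 53.2 ± 8.90 to 99.2 ± 15.5 FPKM. In MHC class I presentation 2 of 11 tested members rose (6 over the list alone), B2m from 34.4 ± 11 to 82.5 ± 13.7 FPKM and Tapbp from 9.11 ± 2.59 to 18.0 ± 1.59 FPKM. The class I heavy chain genes H2-K1 (log2 change 0.03, limma adjusted p = 0.966) and H2-D1 (0.47, limma adjusted p = 0.259) did not pass. Values of H2-K1 and H2-D1 are uncertain because these genes have close copies. Of the 11 members 10 had a change above 0, and 1, Canx, was below (-0.24). In the list named serine, glycine and proline synthesis 3 of 14 tested members fell (4 over the list alone). These were Gldc, from 56.1 ± 10.1 to 25.4 ± 5.71 FPKM, Psat1, from 219 ± 17.5 to 141 ± 10.6 FPKM, and Pycr1, from 8.82 ± 1.08 to 3.04 ± 0.78 FPKM. Gldc encodes a glycine-degrading enzyme, and the list also holds genes such as Atf4 that are not synthesis enzymes. These 3 lists passed camera (adjusted p = 1.46e-04, 0.00743 and 7.35e-04), and none did with an estimated correlation (adjusted p = 0.221, 0.174 and 0.174). In the order of the lists, the numbers past the threshold were 1, 0 and 0 without Q-KO replicate 2, 2, 0 and 0 without Q-KO replicate 3, 1, 0 and 0 without wild-type replicate 1, 4, 0 and 2 without Q-KO replicate 1, and 5, 2 and 2 without wild-type replicate 2. The 7 calls named here were all lost without Q-KO replicate 2, Q-KO replicate 3 or wild-type replicate 1 (adjusted p 0.0568 to 0.196). B2m, Tapbp and Psat1 were lost without Q-KO replicate 1, Grn, Tapbp and Psat1 without wild-type replicate 2, and Psat1 without wild-type replicate 3. With no filter on low values the numbers were 3, 0 and 2 (MHC class I median 0.31), and with the replicate block 5, 2 and 1. The lysosome median was 0.24 after a length trend and 0.25 after a GC trend was removed, the MHC class I median 0.36 and 0.39 (0.51 as designed). The median of the serine, glycine and proline list was -0.25 and -0.24 in these settings (-0.11 as designed). That median moved both ways with a library left out, to -0.04 without Q-KO replicate 1 (6 of 14 above 0) and -0.22 without wild-type replicate 3. With all 6 libraries kept, Psap and Pycr1 passed under each alternative run, and the other 5 of these 7 calls were lost under at least 1. A list picked on these libraries is not independent evidence of its direction.

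The 470 genes past the threshold were set against the other ways to divide the 6 libraries into 3 and 3. There are 10 such splits, too few for a share under 0.05. The real split gave 470 genes, the highest of the others gave 3, and 1 of the 10 splits, the real one, gave as many. Each of the other splits mixes wild-type and Q-KO libraries in its groups, which adds any difference between them to the spread within groups. Such splits can call few genes for that reason alone, so these counts do not measure how many of the 470 calls are false.

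Wild-type replicate 3 differed from the other wild-type libraries in Y-linked transcripts and in genes of chromosomes 8 and 11. A trend with GC content is argued against as the whole cause, since after its removal the medians of chromosomes 8 and 11 in this library were 0.239 and 0.228, against at most 0.025 for its other 17 autosomes (SD 0.024). A swap with a Q-KO library is argued against as well, because Ccnd3 was at 62.3 FPKM in it, against at most 13.2 FPKM in Q-KO libraries, and 0 Q-KO libraries lacked Y-linked transcripts. In the proximal and the distal part of both chromosomes at least 77% of genes lay above the autosomal median, against 44.8% on its other autosomes, which is consistent with extra copies of both chromosomes in part of these cells as a candidate explanation. Whether wild-type replicates 1 and 2 come from another line, or lost the Y chromosome, stays open.

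The mitosis list was lower in Q-KO libraries by camera with a preset correlation, though not with an estimated one (adjusted p = 0.392), and the DNA replication list passed neither. A trend with gene length is argued against as the whole cause, since the mitosis median was -0.74 after that trend was removed. Fewer cells in cycle as the whole cause would lower both lists alike only if both follow the number of cycling cells, which was not tested. The replication median was -0.044 (SD over its members, which go both ways, 0.262), above -0.326, the mitosis median divided by 2. With that premise open, these values do not decide on this cause. The mean of the mitosis list minus that of the replication list was -0.1, -0.03 and -0.24 in wild-type and -0.77, -0.7 and -0.82 in Q-KO libraries, lower in 9 of 9 pairs (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The genotype and a difference between lines both stay open, and a changed share of cells in each phase of the cycle may give such a pattern but was not measured.

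The Rhox family and part of the germline list were higher in the Q-KO libraries. Of the 19 tested germline genes 4 had a change below 0, and of the 18 outside the Rhox family 4 passed the threshold (Asz1, Brdt, Slc25a31 and Taf7l), of which only Asz1 passed without Q-KO replicate 2, Q-KO replicate 3 or wild-type replicate 1, and only Asz1 and Taf7l without Q-KO replicate 1. The median change was 1.501 over the 38 tested members of both lists and 1.017 over the germline list, which did not pass camera with an estimated correlation (adjusted p = 0.686). Most of the tested Rhox genes had a wild-type mean under 1 FPKM, as did Asz1, Taf7l and Slc25a31 (0.595, 0.436 and 0.497 FPKM). These members passed the filter only through their Q-KO values, which favours a rise. How many Rhox genes rose, and how many only took up reads shared between Rhox copies, cannot be told apart, since only 1 tested member, Rhox1, had no value called uncertain and a wild-type mean of at least 1 FPKM. The line of the cells and the genotype cannot be told apart for these genes either, since only 1 wild-type library had Y-linked transcripts (median over the 38 members of wild-type replicate 3 minus wild-type replicates 1 and 2, -0.057, with 7 of them, Rhox6 and Rhox9 among these, highest in wild-type replicate 3).

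Some single libraries held values of their own. Q-KO replicate 1 had 1.16 FPKM of Col1a2, 1.35 of Col3a1, 14.8 of Egr1 and 4.42 of Fos, and the other 5 libraries had at most 0.0442, 0.0322, 0.222 and 0.955. Lefty2 was highest in wild-type replicate 3, at 52.6, 31.0 and 187 FPKM in the wild-type and at 22.7, 4.78 and 10.6 FPKM in the Q-KO libraries. Lefty1 was also highest there, at 19.03, 11.99 and 57.54 FPKM in the wild-type and at 7.632, 1.907 and 3.767 FPKM in the Q-KO libraries. Both genes were lower in each Q-KO library than in any wild-type library, so their difference is not that of a single library alone. Values of Lefty1 and Lefty2 are uncertain because these genes are close copies of each other. Neither passed limma's test over all genes (adjusted p = 0.0834 for Lefty2 and 0.064 for Lefty1). Hmgcs1, an enzyme of cholesterol synthesis, was listed at 0 in all 6 libraries.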
